A study of Caenorhabditis elegans with 2 samples.

How the data were processed

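Chromatin immunoprecipitation followed by sequencing was carried out on whole mixed-sex L2 larvae of the Caenorhabditis elegans strain OP83, which expresses eGFP-tagged ZAG-1 from an insertion. The labels give 2 biological replicates, which were kept as 1 group. No second condition was given, so replicate 1 against replicate 2 was the only comparison between samples.

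Per the deposited file list, peaks of each replicate were made from that replicate's alignment and a control alignment, and a pooled list from both replicates. Per the same deposited file list, an IDR-thresholded list was then made from the replicate lists and the pooled list, in each of 2 builds, ce11 and ce10. The peak caller, its filters and the IDR threshold are not given in the sources used here. The replicate lists are described in the deposited file list as peaks and background, so they also hold weak candidates. Each list gives a score per peak from the authors, a −log10 q-value from the authors and the offset of the summit, all as deposited. In ce11 the deposited −log10 q-values ran from 2.40 to 2.50 in the IDR-thresholded list. The score was used to describe, rank and filter peaks within a list, and to correlate the replicates across shared peaks; its levels were not compared between lists. The IDR-thresholded list was the same as the 1803 highest-scoring peaks of the pooled list. The summit lay at the middle of the peak for 96.3% of its peaks. No signal track, control library or alignment was analysed here, so the depth is unknown and intervals cover counting of peaks only. No pair of peaks in the replicate lists had equal coordinates, so the lists are not copies of each other.

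Genome sequence and annotation were those of WBcel235 (Ensembl release 115 for genes), the same assembly as ce11. The ce10 lists were used only where neither sequence nor annotation was needed. Each summit was placed in the first fitting class of promoter (500 bp upstream to 100 bp downstream of a protein-coding start), coding exon, untranslated region, intron, other transcribed sequence and intergenic sequence. Overlaps needed at least 1 bp and were computed with bedtools 2.31.1, and with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 for the shifts. Figures were drawn with matplotlib 3.10.9.

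Overlap, class and tRNA shares were tested against 1000 circular shifts within chromosomes, two-sided, where the smallest p is 0.0020. Chromosomes were tested with an exact binomial test against length. The CAGGTG E-box was counted within 100 bp of the summit and in a window of the same size 500 bp to one side, drawn at random with a fixed seed, with an exact McNemar test. The other E-boxes and all six-base sequences were counted in the same way. E-box presence against score was tested with 100000 permutations.

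For the gene lists, a summit was assigned to the protein-coding gene with the nearest start within 5 kb. The number of members with a peak was compared with 10000 random lists matched on the decile of each gene's assignable territory, two-sided. Benjamini-Hochberg adjustment was used over classes, chromosomes, E-boxes, six-base sequences and the 31 lists, with a threshold of 0.05. Intervals for shares are 95% Wilson intervals. The lists covered neuronal function and identity, transcription factor families, signalling, other tissues, housekeeping complexes and large gene families. Of the listed symbols, 2 (opt-2, elt-5) were not found in the annotation.

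Named genes followed a rule set with the tests, the gene lists and most alternatives before the data were examined. It took the genes of the 10 strongest IDR-thresholded peaks, zag-1 and all genes of the list tied to it, the 4 members with the strongest peak of each list past the threshold above its matched lists, and at most 2 members of every other list. Peaks on mitochondrial DNA were kept in all results except the chromosome test.

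Alternatives were other overlap rules, the higher-scoring 50% of the peaks, each replicate alone, ce10, uniform placement, other promoter, tRNA and motif windows, shuffled sequence, other gene assignments and other null models. Restriction to nuclear peaks and E-box windows without coding sequence were added after seeing the data. The methods were tested on simulated peaks. With 50% of 1803 peaks planted as shared, 50.6% overlapped, against 1.33% in shifts. With 20% of summits planted at protein-coding starts, 30.8% fell in promoters, against 14.0% in shifts. An E-box planted in 10% of windows raised the share by 9.43 percentage points (exact McNemar p = 3.28e-26), and without planting the exact p was 0.736. Of 200 simulated gene lists, 0.50% of the unchanged ones and 100% of those with 10 of 40 genes added were called at an unadjusted p under 0.05.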

Results

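The study measured where ZAG-1 sits on the genome of Caenorhabditis elegans at the L2 larval stage. ZAG-1 is a zinc finger homeodomain transcription factor of the ZEB family, known for its part in neuron differentiation. The strain OP83 carries an insertion that expresses ZAG-1 tagged with eGFP in an unc-119(ed3) background. Chromatin was immunoprecipitated from whole larvae of both sexes in 2 biological replicates, which form 1 group with no second condition. The authors deposited a list of 24146 peaks for replicate 1, 29374 for replicate 2 and 16325 for the pooled replicates. Their list of peaks past the irreproducible discovery rate (IDR) threshold held 1803 peaks in ce11, of which 1784 were on nuclear chromosomes and 19 on mitochondrial DNA. These 1803 peaks covered 658.7 kb, with a median width of 376 bp, and their scores ran from 29.6 to 449.9 (median 44.6). Read depth is unknown, since peak lists give no counts, and peaks are not independent replicates, so each p-value below describes these libraries. Coordinates are 1-based positions in ce11, and scores are the authors' own.

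The replicates called many of their strongest peaks at the same places. Of the 1803 highest-scoring peaks of replicate 1, 1191 (66.1%, 95% Wilson interval 63.8 to 68.2) overlapped 1 of the 1803 highest-scoring peaks of replicate 2 by at least 1 bp. Circular shifts of the peaks along their chromosomes gave 1.98% on average and 3.11% at most, a 33.3-fold difference (two-sided permutation p = 0.0020, the smallest that 1000 shifts can give). In the other direction the share was 66.3%. Of the IDR-thresholded peaks, 1801 overlapped a peak of replicate 1, 1785 a peak of replicate 2 and 1783 a peak of each. Circular shifts gave 17.8% for replicate 1 and 20.7% for replicate 2. The IDR-thresholded peaks overlapped the 1803 strongest peaks of replicate 1 in 86.7% of cases and those of replicate 2 in 77.5%. Their list was made from the replicate lists and the pooled list, so its overlaps and score correlations are not separate evidence of agreement. Across the 1639 IDR-thresholded peaks with a summit in both replicates, the scores had a Spearman correlation of 0.50 and a Pearson correlation of 0.77, across peaks. With all peaks of each list, the overlap of replicate 1 with replicate 2 was 43.9%, against 20.2% in circular shifts.

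Peaks gathered at promoters and avoided coding sequence. Of the 1803 summits, 729 (40.4%, interval 38.2 to 42.7) lay in a promoter, within 500 bp upstream to 100 bp downstream of an annotated protein-coding start, against 14.1% ± 0.808 (SD over 1000 circular shifts), a 2.86-fold excess. Coding exons held 22 summits (1.22%), 0.0552 times the 22.1% of the shifts. Introns held 357 summits (19.8%, 0.642-fold), untranslated regions 40 (2.22%, 0.653-fold), intergenic sequence 552 (30.6%, 1.18-fold), and other transcribed sequence 5.71% (1.61-fold). The adjusted permutation p was 0.0080 for untranslated regions and 0.0024 for each other class, over 6 classes.

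**Figure D1:**
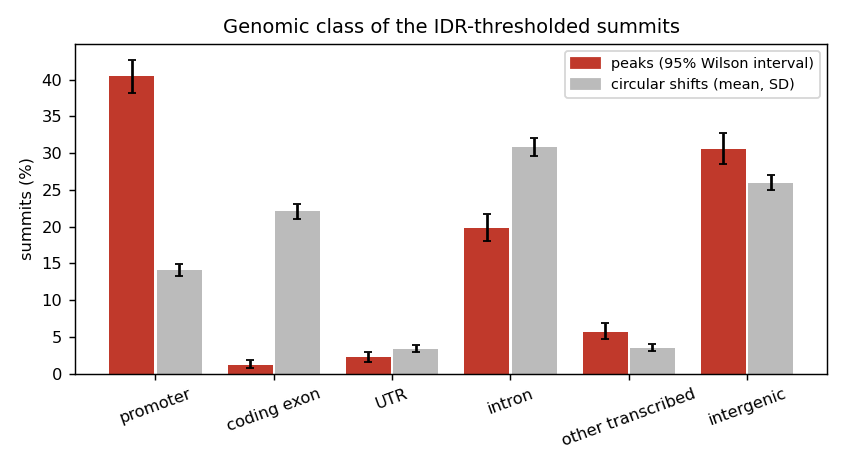
The bars show the percent of the 1803 IDR-thresholded summits in each genomic class (red, with 95% Wilson intervals) and the mean and SD over 1000 circular shifts (grey). Promoters held 40.4% of summits against 14.1% in the shifts, and coding exons 1.22% against 22.1%.

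The highest-scoring nuclear peak lay in the promoter of rpl-3, a protein of the large ribosomal subunit (III, 3867456 to 3867701, score 354). Next came an intergenic peak with W02H3.3 as its assigned gene (X, 11094034 to 11094334, score 324). Promoter peaks followed at tasp-1, a threonine aspartase (III, 10759136 to 10759373, score 274), and at cdc-48.1, an AAA ATPase of protein quality control (II, 10563456 to 10563692, score 268). The promoter of rpl-15, another ribosomal protein gene (IV, 654825 to 655052, score 247), and an intergenic site assigned to klc-1, a kinesin light chain gene (IV, 11082942 to 11083185, score 230.2), completed the nuclear sites among the 10 strongest peaks. The other 4 of these 10 lay on mitochondrial DNA, including the strongest peak of all, in a coding exon of WBGene00010967 (12267 to 12642, score 449.9). The others had WBGene00000829 (4548 to 4923, score 316), WBGene00010960 (2185 to 2560, score 259) and COX3 (5902 to 6277, score 249) as their assigned genes. The COX3 peak ranked 3 in replicate 1 but 3388 in replicate 2. None of the 10 peaks held the sequence CAGGTG or its reverse complement within 100 bp of its summit.

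Transfer RNA genes lay next to 62 summits (3.44%, interval 2.69 to 4.38), counting those within 200 bp. This count includes mitochondrial tRNA genes, while RNA polymerase III transcribes the nuclear ones. The shifts gave 0.679%, a 5.06-fold difference (two-sided permutation p = 0.0020, the smallest that can be given). The size of the excess moved with the choice of peaks. On the nuclear chromosomes alone, a subset chosen after the data were seen, 55 of 1784 summits (3.08%) lay near a tRNA gene. The shifts gave 0.296% there, and the excess was 10.4-fold. Among the higher-scoring 50% of peaks it was 2.92-fold, and with a distance of 500 bp it was 2.94-fold. These settings kept the mitochondrial peaks and were not computed on nuclear peaks alone. They therefore do not show whether the excess was weaker among the stronger nuclear peaks.

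The peaks were unevenly spread over the chromosomes. The X chromosome held 395 peaks, 1.25 times the number given by its length (interval 1.15 to 1.37, two-sided exact binomial test, adjusted exact p = 4.37e-06). It carried 22.3 peaks per Mb against 16.8 on the autosomes, a ratio of 1.32 (exact p = 1.46e-06). Chromosomes I and III also lay above their length, at 1.24 (333 peaks, adjusted exact p = 5.86e-05) and 1.22 (299 peaks, adjusted exact p = 0.000455). Chromosome V, with 240 peaks, lay lowest at 0.645 (interval 0.570 to 0.725, adjusted exact p = 4.09e-15). Chromosome IV stood at 0.864 (269 peaks, adjusted exact p = 0.0096) and chromosome II at 0.912 (248 peaks, adjusted exact p = 0.12). Scaled by protein-coding genes in place of length, chromosome IV was at 0.918 (adjusted exact p = 0.13) and chromosome II at 0.805 (adjusted exact p = 0.000157), so the calls on these 2 chromosomes depended on the scale.

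The E-box CAGGTG, which reads CACCTG on the other strand and is the site type that ZEB proteins bind, was rarer at summits than beside them. It lay within 100 bp of 34 of 1803 summits (1.89%, interval 1.35 to 2.62) and in 102 control windows of the same size centred 500 bp away (5.66%, interval 4.68 to 6.82), a ratio of 0.333 (exact McNemar test, two-sided p = 9.24e-10). The 1803 strongest peaks of replicate 2 alone gave 0.533 (exact p = 0.000323) and those of replicate 1 alone 0.330. Within 50 bp of the summits 21 such E-boxes were found, against 50.9 per 100 bp at 500 to 1000 bp. Of the other E-boxes, 4 were more frequent at summits, as were 747 of all 2080 six-base sequences. Summit windows were richer in GC than control windows (45.6% against 35.2%). These 4 E-boxes were not compared with shuffled windows, so base composition was not held fixed for them. CACATG was found in 12.2% of summit windows against 6.60% of control windows (1.85-fold, adjusted exact p = 2.99e-08 over 10 E-boxes), CAGCTG in 6.21% against 3.83% (1.62-fold, adjusted exact p = 0.0025), CACGTG in 4.66% against 2.83% (1.65-fold, adjusted exact p = 0.010) and CAAGTG in 12.1% against 8.04% (adjusted exact p = 0.000225). CAATTG was also rarer at summits, in 6.21% against 8.15% (0.762-fold, adjusted exact p = 0.049), and CAAATG, CAACTG, CAGATG and CATATG were not past the threshold.

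**Figure D2:**
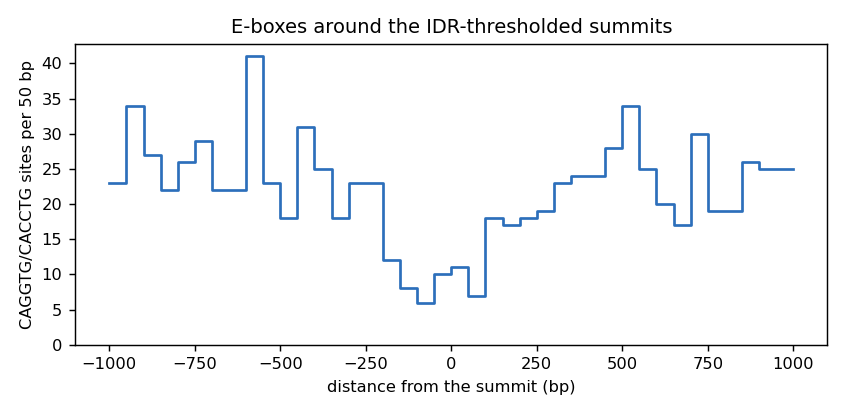
The line shows the number of CAGGTG or CACCTG sites in each 50 bp bin around the 1803 IDR-thresholded summits, from -1000 to 1000 bp. The lowest counts, 6 and 7 sites, lie 50 to 100 bp from the summits, and the bins next to the summits hold 10 and 11.

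A pair of peaks among the 20 strongest nuclear ones held this E-box; they are named after their values were seen. At F20B6.9 (X) the site lay at an offset of 43 bp from the summit in GGGAGCTCAGGTGCGCGCGT (4209297 to 4209316), and at an intergenic X peak with no gene assigned it lay at 38 bp in TACTAGCCACCTGAATACTA (13700881 to 13700900). Among named gene-list members, lin-41 and fbxb-58 had a summit with the E-box.

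Of all 2080 six-base sequences, counted with their reverse complements, 747 were more frequent at summits and 625 less frequent (exact McNemar test, adjusted p under 0.05). GAGAGA led, in 49.4% of summit windows against 9.37% of control windows (5.27-fold, adjusted exact p = 1.93e-146). CGTCTC (33.5% against 5.93%, adjusted exact p = 5.59e-94), ACGCAG (27.3% against 3.99%, adjusted exact p = 4.11e-84) and CACACA (30.3% against 9.15%, adjusted exact p = 1.17e-56) were also more frequent. TTAAAA was found in 17.1% of summit windows against 47.1% of control windows (adjusted exact p = 4.76e-79). GC content was 45.6% ± 6.83 (SD, 1803 windows) at summits and 35.2% ± 7.43 in control windows.

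Stronger peaks did not hold the CAGGTG E-box detectably more often. It was found in 2.00% of the strongest of 4 score quartiles (9 of 451, interval 1.05 to 3.75), in 2.22% of each of the following ones (10 of 451) and in 1.11% of the weakest (5 of 450, interval 0.476 to 2.57). Presence and score had a Spearman correlation of 0.021 across the 1803 peaks (permutation test with 100000 resamples, p = 0.376).

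Genes that work in all neurons carried peaks far more often than matched genes. Of the 1803 summits, 1703 were assigned to the protein-coding gene with the nearest start within 5 kb, at a median distance of 656 bp, which gave 1451 genes with a peak (7.26% of 19985). Of 25 pan-neuronal genes, 22 had a peak (88%, interval 70.0 to 95.8), against 13.4% expected from random lists matched on the territory of each gene (6.56-fold). The strongest peaks of this group lay at egl-3, a neuropeptide-processing protease (V, 10174618 to 10174993, intergenic, score 116), rab-3, a synaptic vesicle GTPase (II, 5725128 to 5725503, intron, score 93.4), unc-104, a kinesin that carries synaptic vesicles (II, 6992927 to 6993302, intergenic, score 85.7), and unc-10, an active zone protein (X, 7284723 to 7285098, intergenic, score 82.5). The 3 members without an IDR-thresholded peak, ehs-1, ric-19 and unc-18, were named after the result was seen. Of 31 gene lists tested, 4 were past the threshold above their matched lists and 3 below (two-sided permutation over 10000 random lists, Benjamini-Hochberg). The adjusted p of the 4 lists above was 0.0010, from the smallest p that the random lists can give.

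Heterochronic genes, which set the timing of larval cell fates, formed another group above its matched lists, with 10 of 15 members (66.7%, interval 41.7 to 84.8, 14.3% expected, 4.66-fold). Peaks lay at lin-42, a period homolog (II, 1246822 to 1247197, intron, score 93.3), lin-41, which encodes a TRIM protein (I, 9343793 to 9344168, intergenic, score 92.2), ain-1, a microRNA cofactor gene (X, 16612447 to 16612541, intergenic, score 89.5), and lin-14, a temporal transcription factor gene (X, 11467320 to 11467695, intron, score 84.1). There were 3 peaks assigned to lin-14.

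Ribosomal protein genes had peaks at 26 of 79 members (32.9%, interval 23.6 to 43.9), 6.37 times the expected 5.17%. After rpl-3 and rpl-15, the strongest were the promoter peaks of rpl-35 (III, 7854566 to 7854794, score 189) and rps-1 (III, 4475595 to 4475736, score 126). Nuclear genes of oxidative phosphorylation had peaks at 11 of 45 members (24.4%, interval 14.2 to 38.7, 4.53-fold). These included the promoters of cox-5B (I, 9788616 to 9788813, score 182) and cox-5A (III, 12905149 to 12905251, score 126), both subunits of cytochrome c oxidase. Promoter peaks also lay at atp-1, a subunit of ATP synthase (I, 12652054 to 12652429, score 85.4), and at sdha-1, a subunit of succinate dehydrogenase (X, 8546022 to 8546397, score 66.0).

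Chemoreceptor genes, F-box genes and neuropeptide and amine receptor genes had fewer peaks than their matched lists. Only 6 of 1299 chemoreceptor genes had a peak (0.462%, 0.0819-fold, adjusted permutation p = 0.0010), the strongest at srw-60 (score 72.7), and srd-43 had a score of 53.9. F-box genes had 4 of 315 (1.27%, 0.225-fold, adjusted permutation p = 0.0010), among them fbxb-58 (score 139) and fbxb-85 (score 58.6). Neuropeptide and amine receptor genes had 5 of 127 (3.94%, 0.285-fold, adjusted permutation p = 0.0027), with peaks at npr-23 (score 84.7) and npr-13 (score 74.5). In the higher-scoring 50% of peaks the F-box list was no longer past the threshold (0.328-fold, adjusted permutation p = 0.14), and neither was the receptor list with no matching (0.542-fold, adjusted p = 0.34 by Fisher's exact test).

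**Figure D3:**
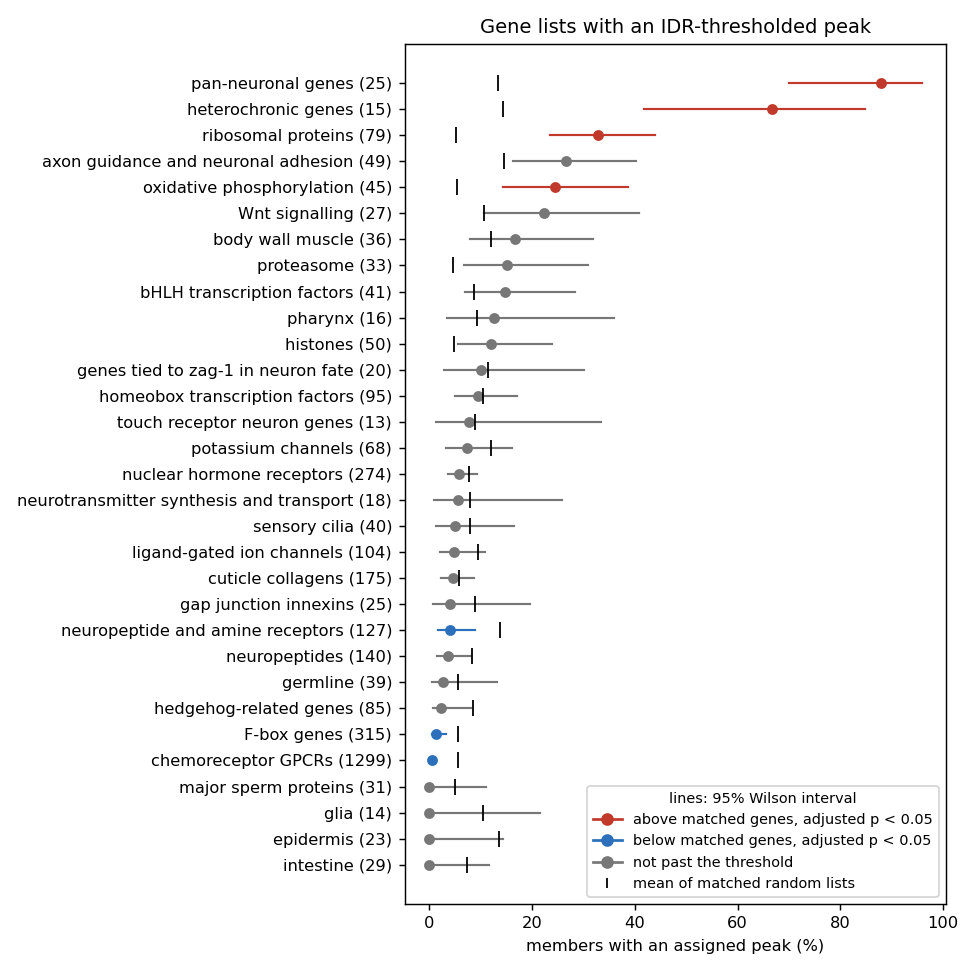
Points show the percent of members with an assigned IDR-thresholded peak for each of 31 gene lists (number of members in parentheses), with 95% Wilson intervals, and black ticks the mean of matched random lists. Pan-neuronal genes stand at 88% against 13.4% expected, and chemoreceptor genes at 0.462%.

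The remaining 24 lists were not past the threshold with the planned assignment and matched lists. Among the neuronal ones, axon guidance and adhesion genes had 13 of 49 members with a peak (1.82-fold, adjusted permutation p = 0.11), with unc-115 (score 91.4) and unc-14 (score 75.8) highest. Neuropeptides had 5 of 140 (0.428-fold, adjusted permutation p = 0.11), including ins-13 (score 173) and ins-39 (score 152). Ligand-gated channels had 5 members with a peak (4.81%; lgc-21, unc-63), potassium channels 5 of 68 (slo-1, unc-103), innexins 1 of 25 (unc-9), sensory cilia 2 of 40 (klp-11, daf-19), neurotransmitter synthesis and transport 1 of 18 (snf-11) and touch receptor genes 1 of 13 (mec-12). Among regulators, homeobox genes had 9 of 95 (ceh-38, ceh-5), bHLH genes 6 of 41 (hif-1, mdl-1), nuclear hormone receptors 16 of 274 (nhr-48, nhr-88) and Wnt signalling 6 of 27 (mig-5, cam-1). Tissue lists held 6 of 36 for body wall muscle (act-4, dyb-1), 2 of 16 for pharynx (ceh-22, phat-6), 8 of 175 for collagens (col-94, dpy-10), 2 of 85 for hedgehog-related genes (ptc-1, ptr-5) and 1 of 39 for germline (spo-11). The spo-11 peak ranked 596 in replicate 1 but 24613 in replicate 2. No peak was assigned to any of 29 intestine, 23 epidermis, 14 glia or 31 major sperm protein genes. The upper interval bounds were 11.7% for intestine, 14.3% for epidermis and 21.5% for glia. Matched lists were expected to have only 2.14, 3.10, 1.45 and 1.57 members with a peak, in the order given. These counts therefore do not show that peaks avoid such genes (adjusted permutation p from 0.17 to 0.63). The proteasome list had 5 of 33 members with a peak (rpn-3, rpn-11, 3.33-fold, adjusted permutation p = 0.11) and the histone list 6 of 50 (his-37, his-24, 2.46-fold, adjusted permutation p = 0.17). With the strongest peaks of replicate 2 alone the proteasome list passed the threshold (4.94-fold, adjusted permutation p = 0.0089), and with those of replicate 1 alone the neuropeptides did (0.347-fold, adjusted permutation p = 0.047). With gene bodies or 2 kb upstream in place of the nearest start, axon guidance (1.87-fold, adjusted permutation p = 0.047) and histones (2.59-fold, adjusted permutation p = 0.047) passed above. In the same setting neuropeptides (0.302-fold, adjusted permutation p = 0.050, just under the threshold) and ligand-gated channels (0.233-fold, adjusted permutation p = 0.0046) passed below. Ligand-gated channels also did so within 1 kb, with 0 members (adjusted permutation p = 0.035). With no matching, axon guidance (3.65-fold, adjusted p = 0.000169) and Wnt signalling (3.06-fold, adjusted p = 0.044) passed above by Fisher's exact test. Against circular shifts, histones (4.98-fold, adjusted permutation p = 0.015) and the proteasome (4.10-fold, adjusted permutation p = 0.048) did.

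The gene zag-1 itself (WBGene00006970, IV, 3855843 to 3861569, plus strand) had no peak in any of the 4 ce11 lists. Genes tied to zag-1 in neuron fate had peaks at 2 of 20 members (0.874-fold, adjusted permutation p = 1), lin-14 and unc-119 (III, 10903226 to 10903601, intron, score 42.1). No IDR-thresholded peak was assigned to the transcription factor genes ahr-1, alr-1, ceh-28, egl-44, egl-46, lin-11, mec-3, ttx-3, unc-4, unc-30 and unc-86. The same held for the effector genes glr-1, mec-4, mec-7, ser-7, tph-1, unc-25 and unc-47. Around zag-1, the summits nearest on either side were at 3838181 and 3894440 in the pooled list, 56.3 kb apart (rank 51 of 16299 gaps from the longest, median 3.09 kb). In replicate 1 they were 49.7 kb apart (rank 14 of 24119, median 2.38 kb), and in replicate 2 they lay at 3841007 and 3890977 (rank 5 of 29352, median 2.10 kb). In the IDR-thresholded list the gap of 180.4 kb ranked 113 of 1778.

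**Figure D4:**
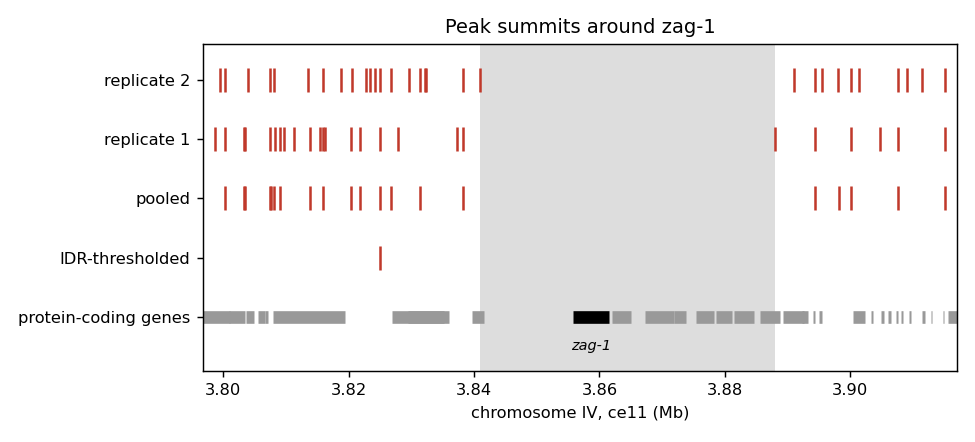
Ticks show the peak summits of each list along chromosome IV (ce11, Mb) around zag-1 (black), with other protein-coding genes in grey. The shaded stretch, from 3841007 to 3888008, holds no summit of either replicate.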

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

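The comparison of mitochondrial with nuclear summits was chosen after its result was seen, and the test by rotation after the peaks were seen but before its result. Mitochondrial DNA, which lies outside the test of the nuclear chromosomes, held 19 of the 1803 IDR-thresholded peaks, a signal in data that no comparison of chromosomes used. The density was 1.38 peaks per kb against 0.0178 per kb of nuclear sequence, and 5 of the 20 strongest peaks were mitochondrial. Reads on abundant mitochondrial DNA, called as peaks along the molecule, may account for them: 42.1% of the mitochondrial summits (8 of 19, interval 23.1 to 63.7) had a summit within 100 bp in each replicate, against 91.4% of nuclear summits (Fisher's exact test, p = 1.02e-07). A few discrete sites on the molecule also stay open: 9 of the 21 summits of replicate 1 lay within 100 bp of 1 of the 16 of replicate 2, against 4.89 on average over all rotations of its 13.8 kb (one-sided exact permutation p = 0.022). The tests do not decide between these explanations, enrichment over the control library was not analysed here, and no biological explanation was tested.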

How the results depend on the processing

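Restriction to nuclear peaks and to windows without coding sequence was chosen after the results were seen; the other alternatives were planned. Of 356 values computed under an alternative, 340 kept their side of the threshold, and their direction where it was compared, or lay close to the value reported. Another 12 came past the threshold, 3 fell short of it and 1 count changed by over 1.5 times. No value compared for direction turned. Direction was not compared for gene lists short of the threshold in both settings, and some of these turned. Neurotransmitter synthesis and transport, for example, went from 0.700-fold to 1.41-fold with replicate 2 alone. With gene bodies or 2 kb upstream in place of the nearest start, 5 lists lay below their matched lists, against 3; the cause was not tested. The number of lists above was 6 in that setting, with no matching and with circular shifts, against 4. The pan-neuronal, heterochronic, ribosomal and oxidative phosphorylation lists kept their call in 8 of 8 settings. With 1 replicate alone, the promoter excess ranged from 2.71 to 2.76, the tRNA excess from 4.56 to 7.22, the X peaks over the number by length from 1.24 to 1.32, the X to autosome ratio from 1.30 to 1.42, the E-box ratio from 0.330 to 0.533 and the number of lists above from 4 to 5. The E-box ratio was 0.343 with control windows 1000 bp away, 0.447 within 50 bp and 0.393 in the 1193 window pairs without coding sequence. Replicate agreement ranged from 43.9% with all peaks to 68.6% in the higher-scoring 50%. Read depth per library was not analysed here, so its effect on the number of peaks is open. No paired analysis was possible because the libraries form 1 group.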

Other observations

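Of the tests reported here, the E-box ratio to shuffled windows was planned, and those of all pooled peaks under the threshold, of the spacing of peaks at zag-1 and of repeats were set before their result was seen. The tests of peaks by gene list, of chromosome centres, of the pooled peaks by score, of tissue genes and of other long stretches were chosen after the results were seen. Peaks of the pan-neuronal and the ribosomal protein genes differed in place. Of 26 peaks at ribosomal protein genes, 100% lay in promoters, and of 30 peaks at 22 pan-neuronal genes 33.3% did (Fisher's exact test, adjusted p = 1.27e-07 over 2 tests). The test counted peaks of the same gene separately and did not allow for the territory of the genes. Lists matched on territory were expected to have a peak at 5.17% of ribosomal and 13.4% of pan-neuronal members. No expected promoter share was computed per list. GAGAGA lay near 17 of the pan-neuronal summits (56.7%) and 7 of the ribosomal ones (26.9%, adjusted exact p = 0.032), and CAGGTG near none of either. GAGAGA itself varied with place over all peaks, at 306 of 729 promoter, 184 of 357 intronic (51.5%) and 324 of 552 intergenic summits (58.7%), so its difference between the lists is not separate from that in place. Heterochronic genes had 3 of 15 peaks in promoters, and oxidative phosphorylation genes 10 of 11. The sequence GAGACGCAGA, joined from overlapping six-base sequences that led the ranking, lay in 227 summit windows (12.6%) and 12 control windows (0.666%); it was picked on these windows, so no test of it is given. It was found in 15.8% of intergenic, 12.1% of promoter and 10.9% of intronic summit windows.

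Several genes held more than 1 peak. The G protein subunit gene gpb-1, let-526 and pqn-41 had 5 each, and daf-16, din-1, kin-1, mdl-1, ncl-1, ncs-2, nhr-3, pde-4 and sma-9 had 4 each. The central 33.3% of chromosome I held 50.5% of its peaks and that of chromosome V 120 of 240 (exact binomial test, adjusted p = 8.94e-10 and 3.12e-07). Chromosomes II (45.6%, adjusted exact p = 9.87e-05), III (40.1%, adjusted exact p = 0.017) and IV (45.7%, adjusted exact p = 4.90e-05) also lay above 33.3%. On the X chromosome the share was 32.7% (adjusted exact p = 0.79). The expected 33.3% came from length alone and was not scaled by genes, so gene content was not held fixed. Pooled peaks under the IDR threshold were assigned to 14 of the 20 genes tied to zag-1 and 9 of the 13 touch receptor genes. Shares were as high or higher in other lists, with 18 of 23 epidermis, 28 of 36 body wall muscle and 102 of 127 receptor genes, so these counts do not set the former apart; none was tested. All 25 pan-neuronal genes had a pooled peak above or under the threshold.

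Peaks lay at tRNA and ribosomal protein genes, yet few of all peaks held the CAGGTG E-box, with a ratio of 0.333 to control windows. Base composition as the reason for its rarity is argued against by a ratio of 0.337 to shuffled summit windows (exact p = 3.70e-09). Signal at highly transcribed genes of any tissue stays open: muscle, collagen and intestine genes together had 14 of 240 members with a peak (0.846-fold, permutation p = 0.61), and transcription was not measured here. Whether E-box sites lie among the 14522 weaker pooled peaks also stays open, with a ratio of 0.982 (exact p = 0.74), which was 0.721 in the highest-scoring of 4 parts (adjusted exact p = 0.023) and 1.29 in the lowest (adjusted exact p = 0.026). Binding of other factors at the same places was not tested.

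None of the 4 ce11 lists had a peak over zag-1, and a stretch from 3841007 to 3888008 on chromosome IV held no summit of either replicate. Chance spacing of peaks stays open. As long a stretch lay over the gene in 2 of 1000 joint circular shifts of the replicate lists (permutation p = 0.0030). These shifts keep the gaps between peaks, so the test shows only that so long a stretch rarely falls on a given place. It cannot tell how the stretch arose. The stretch was not rich in masked repeats, since its masked share of 26.5% lies at the 18.1st percentile of windows of its length (median 32.2%). Masking does not measure whether reads can be placed, so sequence on which reads cannot be placed stays open. Extra copies of the locus in the inserted strain, which could raise the control signal there, cannot be told apart from other causes, because 3 other stretches were as long, on V (220.0 kb, 46.8% masked, and 88.8 kb, 15.6% masked) and III (58.5 kb, 85.5% masked), and at least the last is itself rich in repeats. Removal of the region by the authors was not tested, and no biological explanation was tested.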
